A study of Sus scrofa with 150 samples.

How the data were processed

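Liver RNA of 150 pigs of a commercial cross was hybridised to the Affymetrix Porcine Genome Array, 1 array per pig. The labels put all 150 pigs in a single group, with no treatment and no control, and give 2 traits for each pig: the fat area on the long back muscle at the last ribs, in cm2, and the drip loss of that muscle, in percent of its weight. Both traits were used as the labels give them. The labels do not give sex, family, slaughter day or array batch. The titles carry a number for each pig whose meaning is not given, and it was used only as a possible order or batch.

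The deposited table holds log2 values per probe set, with 2 decimals; that the scale is log2 was read from the values, and the submitters' processing notes name GCOS 1.1.1 (Affymetrix's scanner software). The summary method, background correction and normalization are not given in the sources used here. The lowest value was 4.09 on the log2 scale on every array, which equals the log2 of 1 plus 16 within rounding, and 2.75% of all values lay at this floor. A change in a probe set near the floor is therefore understated. The array medians ran from 5.79 to 6.09 on the log2 scale. Each array correlated with the others at a median r of 0.968 on average (SD 0.00799, n = 150), the lowest being 0.928. An array whose median correlation lay over 3 median absolute deviations (MAD) below the median of all arrays was counted as standing apart, and 13 did. No array correlated with another above 0.989, so no array was taken for a copy of another. The log2 difference between the 3 prime and 5 prime control probe sets, a sign of RNA integrity, averaged 0.921 (SD 0.258, n = 150) for GAPDH and 2.86 (SD 0.451, n = 150) for beta-actin. The number of arrays limits the precision.

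Of 24123 probe sets, 124 Affymetrix controls were left out and 23999 were tested. Gene names came from the array's annotation, updated by Entrez ID through the pig gene table of the assembly Sscrofa11.1; 10069 probe sets had 1 symbol, 198 had several and 13732 had none. The 10069 covered 6765 symbols; 9961 were matched by Entrez ID, 108 kept the annotation's symbol, and the update changed 0. No gene was named from a probe set with several symbols, and no coordinates are given because the files name no genome build.

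The slope of each probe set on each trait, divided by the trait's SD over the pigs, was fitted with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, without covariates, and called at a Benjamini-Hochberg adjusted p under 0.05 over the 23999 probe sets. All tests were two-sided. Both traits in a single model gave the test of the difference between the slopes. Of 35 gene lists, 34 had at least 2 probe sets and were tested with camera (preset inter-gene correlation 0.01, and again with the correlation estimated) and with fry, adjusted over the 68 tests of both traits. Probe sets of a gene all entered the set tests, and a gene counted once in the counts, by its probe set of smallest p. Adjustment over a list alone does not allow for the choice of probe set or for the other lists. It uses the same slopes as the set tests, so it is no separate evidence for a list. Correlations across pigs had permutation tests of 100000 resamples, whose smallest possible p is 1e-05, and were repeated without the 2 pigs farthest from the median of the measure on the x axis. The pairs of traits were permuted together over the pigs 99 times for the counts. Folds compare the means of the 30 pigs with the highest and the 30 with the lowest trait value. Tested on simulated data with 200 changed probe sets among the 23999, the fit for fat area recovered 53% of those simulated at a correlation of 0.3, 98% at 0.4 and 100% at 0.5. For drip loss it recovered 53.5%, 94% and 100%. Wrong calls numbered 77 of 183, 3 of 199 and 31 of 231 in the runs for fat area and 4 of 111, 51 of 239 and 8 of 208 in those for drip loss, so the share of wrong calls varied widely around the nominal 5%, and lists of calls should be read with that in mind. With 1 gene list simulated as changed, the preset camera test ranked it 1 and passed 3 lists, so 2 passed that were not simulated, and lists called only by the preset test are weak evidence.

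The design, the gene lists and the rule for naming genes were fixed before the data were examined. Per trait the rule named, among called probe sets with a single symbol, the 10 with the largest positive and the 10 with the largest negative slope, 1 per gene, and up to 4 called members of each list. A direction with fewer than 5 had its 5 smallest p named, and the 3 lists of smallest camera p had up to 4 members named whether or not they passed. The difference test named 5 genes per direction, and correlations were given for at most 6 genes per trait. Any other gene named was chosen after its values were seen. The alternatives were quantile normalization, filters on dim or flat probe sets (an SD above 0.25), other eBayes settings, normal scores and other thresholds. Covariates tried were the other trait, the title number (a spline with 4 df, or blocks of 100), the 3 prime to 5 prime differences, 5 principal components, the mean of 2 Y-linked probe sets and red blood cell markers. The fits were also repeated without the 2 most extreme pigs, on the tails of 30 pigs alone, and without arrays that stand apart. The array median as a covariate, the Y-linked mean together with 5 principal components, and the gene lists with the Y-linked mean or without arrays that stand apart were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.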

Results

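Livers of 150 slaughtered pigs were profiled on 1 array each. Fat area averaged 15.2 cm2 (SD 3.25, n = 150) and ran from 8.1 to 26.7 cm2. Drip loss, the water a piece of muscle loses on hanging, averaged 5.54% (SD 2.12, n = 150) and ran from 1.45 to 10.82%. The 30 pigs with the largest fat area averaged 20.2 cm2 and the 30 with the smallest 11.3 cm2. The 30 pigs with the highest drip loss averaged 8.52% and the 30 with the lowest 2.58%.

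Fat area and drip loss were hardly related to each other. Pearson's r was -0.0794 (permutation p = 0.333; 95% interval -0.237 to 0.0819; n = 150) and Spearman's rho was -0.0544 (permutation p = 0.51). Without the 2 pigs farthest from the median fat area r was -0.0664. This was 1 of 16 relations among traits and array measures, with adjusted p values of 0.493 for r and 0.816 for rho. Drip loss also went with the number in the titles, with r = -0.26 (permutation p = 0.0014, adjusted p = 0.0056) and rho = -0.229 (permutation p = 0.00527, adjusted p = 0.0169), and r was -0.218 without the 2 pigs with the most extreme numbers. Blocks of 100 title numbers, 10 in all, held 17.9% of the variance of drip loss (permutation p = 0.0006) and 7.58% of that of fat area (permutation p = 0.259). Drip loss went with the 3 prime to 5 prime difference of actin as well, with r = 0.246 (permutation p = 0.00239, adjusted p = 0.00765) and rho = 0.233 (permutation p = 0.00422, adjusted p = 0.0169), and r was 0.245 without 2 pigs. For fat area the corresponding r was 0.0132 (permutation p = 0.873) and rho 0.039 (permutation p = 0.634).

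The comparison of liver expression with fat area asked which transcripts were higher or lower in pigs with more back fat. Among the named genes, GPT and BCKDHB of amino acid breakdown were higher in pigs with a larger fat area, and ASNS and ALDH18A1 of amino acid synthesis were lower. No list of amino acid synthesis was tested, so ASNS and ALDH18A1 do not stand for such a group. GPT, the alanine aminotransferase, rose by 0.14 (SE 0.031) on the log2 scale per SD of fat area, a 1.32-fold difference between the 30 highest and the 30 lowest pigs. BCKDHB, a subunit of the enzyme complex that degrades branched-chain amino acids, rose by 0.10 (SE 0.022), or 1.22-fold. ASNS, which makes asparagine, fell by 0.17 (SE 0.039), with a ratio of the tails of 0.721. ALDH18A1, an enzyme of proline and ornithine synthesis, fell by 0.15 (SE 0.033), with a ratio of 0.723. The adjusted p was 0.0115 for GPT, BCKDHB and ALDH18A1 and 0.0228 for ASNS (limma, n = 150). The tails also differed in the Y-linked gene EIF1AY. Its mean was 6.06 in the 30 highest and 4.66 in the 30 lowest pigs on the log2 scale. Folds between these tails therefore do not separate fat area from the level of Y-linked transcripts.

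DBP, a transcription factor that follows the circadian clock, had a slope of 0.22 (SE 0.05, adjusted p = 0.0231), or 1.56-fold between the tails. APCDD1, an inhibitor of Wnt signalling, rose by 0.14 (SE 0.031, adjusted p = 0.0228). FN3K, which removes sugar adducts from proteins, rose by 0.13 (SE 0.03, adjusted p = 0.0286). ABHD14B, a hydrolase-fold protein, rose by 0.11 (SE 0.024, adjusted p = 0.0115). PRDX6, a peroxiredoxin, rose by 0.10 (SE 0.022, adjusted p = 0.0192), and CST3, the secreted protease inhibitor cystatin C, by 0.08 (SE 0.018, adjusted p = 0.0302). IER5, an immediate early gene, fell by 0.14 (SE 0.033, adjusted p = 0.0231), while its other 2 probe sets had slopes of -0.034 (p = 0.276) and -0.043 (p = 0.0291) and were not called. A probe set annotated as B2M, the light chain of MHC class I, fell by 0.13 (SE 0.029, adjusted p = 0.0183), but the other 8 probe sets annotated as B2M had slopes from -0.034 to 0.058, the smallest p being 0.0696, and correlated with it at -0.247 to 0.0797. TMEM248, a membrane protein, did not pass (slope -0.09, SE 0.022, adjusted p = 0.0631). The largest named slope was that of the Y-linked EIF1AY, at 0.45 (SE 0.088, adjusted p = 0.00412).

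**Figure D1:**
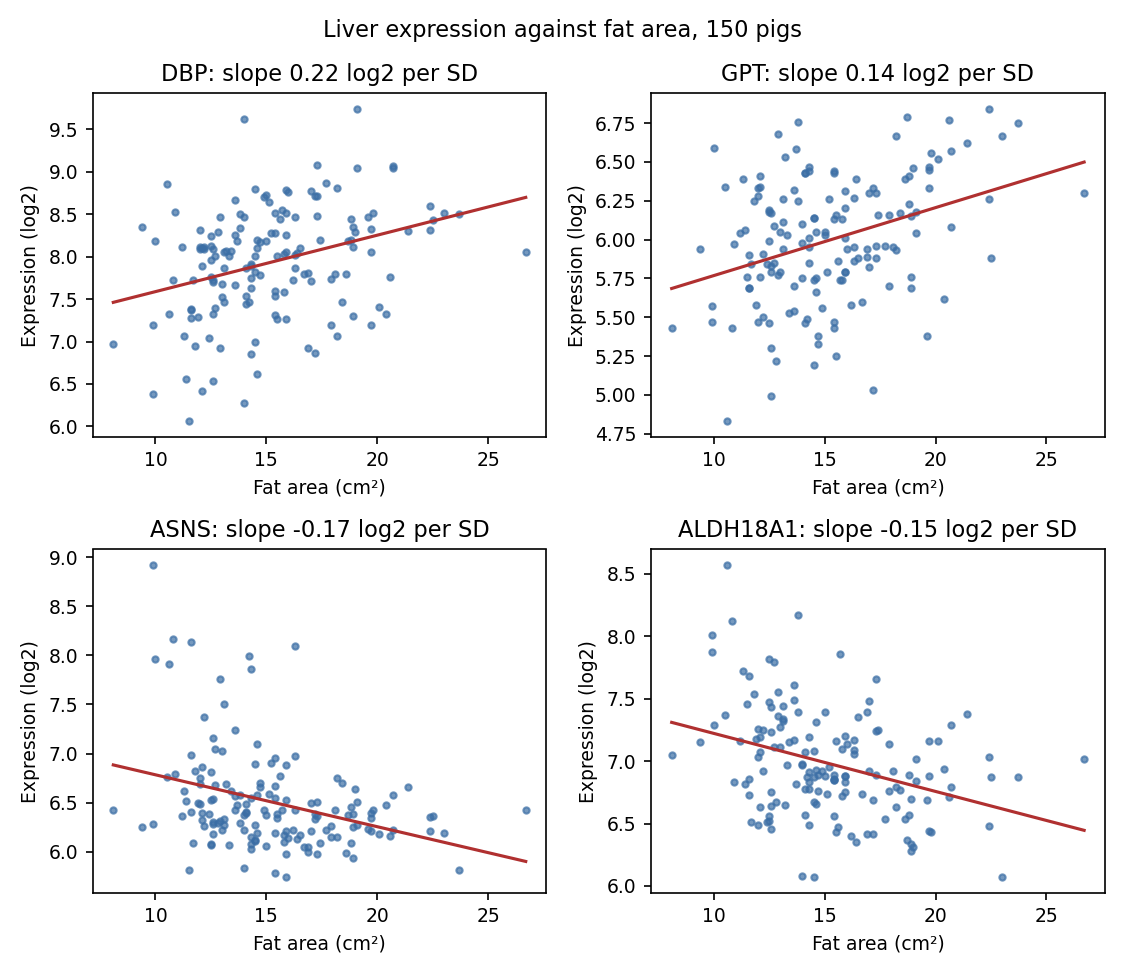
Expression (log2) of DBP, GPT, ASNS and ALDH18A1 against fat area (cm2), with a point for each of 150 pigs and the least-squares line in red. DBP and GPT rose by 0.22 and 0.14 per SD of fat area, while ASNS and ALDH18A1 had slopes of -0.17 and -0.15, with a wide scatter around each line.

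In all, 30 of 23999 probe sets were called for fat area, 19 higher and 11 lower with more fat, and 13 of them carried a gene symbol. At an unadjusted p under 0.05 there were 1699, against 1200 expected from uniform p values; permuting the traits over the pigs gave a median of 911 and up to 4820, so this number lay within the permuted range. Of the 30 called, 10 correlated with the mean of the Y-linked probe sets at an absolute r between 0.826 and 0.983, and they included EIF1AY and the largest slopes, from -0.86 to 0.98, both ends being probe sets without a symbol. With the Y-linked mean as a covariate 1 probe set was called, which has no symbol (slope 0.21, SE 0.04, adjusted p = 0.0132). None of the named genes stayed called; the slopes of those outside that set of 10 were, for example, 0.14 for GPT (SE 0.033, adjusted p = 0.127), 0.21 for DBP (SE 0.054, adjusted p = 0.214), 0.08 for BCKDHB (SE 0.023, adjusted p = 0.237) and -0.13 for ASNS (SE 0.042, adjusted p = 0.326). With 5 principal components as covariates 68 probe sets were called higher and 34 lower, and 24 of the 30 were among them.

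**Figure D2:**
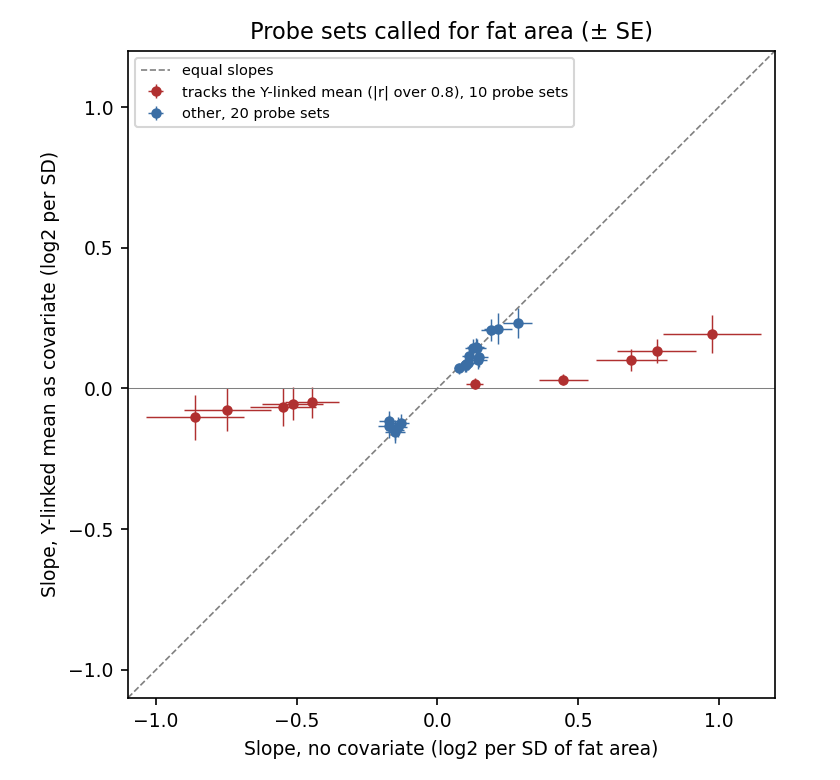
Slopes on fat area (log2 per SD, with SE) of the 30 called probe sets, without a covariate on the x axis and with the Y-linked mean as a covariate on the y axis. The 10 probe sets chosen for tracking the Y-linked mean (red) lie far from the dashed line of equal slopes, with a median absolute slope of 0.62 before and 0.07 after, and the other 20 (blue) lie near it, at 0.14 and 0.13.

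Single relations with fat area were moderate. For BCKDHB Pearson's r was 0.36 (permutation p = 1e-05, the smallest possible) and rho 0.369 (permutation p = 2e-05), and for GPT r was 0.353 (permutation p = 2e-05) and rho 0.294 (permutation p = 0.00027). For ALDH18A1 r was -0.352 (permutation p = 2e-05) and rho -0.339 (permutation p = 1e-05). For ASNS r was -0.335 (permutation p = 5e-05) and rho -0.325 (permutation p = 6e-05), and for the same B2M probe set r was -0.343 (permutation p = 4e-05) and rho -0.302 (permutation p = 0.00022). Without the 2 pigs of most extreme fat area r was 0.354 for BCKDHB, 0.328 for GPT, -0.376 for ALDH18A1, -0.331 for ASNS and -0.305 for B2M. Given the spline of the title number, the partial r was 0.375 for BCKDHB, 0.351 for GPT, -0.385 for ALDH18A1, -0.356 for ASNS and -0.349 for B2M. Given the Y-linked mean it was smaller for each, at 0.285, 0.334, -0.323, -0.255 and -0.301 in the same order. Across the 12 relations computed for both traits the adjusted p values of r for these genes were between 4.8e-05 and 8.57e-05, and those of rho between 6e-05 and 0.000305; the genes had been picked from 23999 probe sets for this relation, which these p values do not allow for. EIF1AY values fell into 2 clusters, 73 pigs up to 4.72 and 77 pigs from 5.64 on the log2 scale, so no pooled r is given; within the lower cluster r with fat area was -0.0619 (permutation p = 0.595) and rho -0.113, and within the upper cluster r was -0.0746 (permutation p = 0.518) and rho -0.0833.

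Among the gene lists, amino acid catabolism and the urea cycle stood out with fat area. Of its 17 measured genes 16 had a positive slope; 2 rose over all genes tested, BCKDHB and GPT, and 10 rose when adjusted over the list alone, with 0 lower. The list's median slope was 0.08, and camera gave an adjusted p of 6.42e-16, with 0.0024 with an estimated correlation and 0.000485 with fry. FAH, the last enzyme of tyrosine breakdown, had a slope of 0.07 (SE 0.019, adjusted p = 0.102 over all genes and 0.00161 over the list alone). GNMT, a glycine methyltransferase of the methionine cycle, had 0.13 (SE 0.037, adjusted p = 0.139 and 0.00167). ASL, an enzyme of the urea cycle, had 0.11 (SE 0.03, adjusted p = 0.144 and 0.00167), and SDS, the serine dehydratase, 0.36 (SE 0.122, adjusted p = 0.305 and 0.00949). The mean of the list correlated with fat area at r = 0.356 (permutation p = 2e-05) and rho = 0.352 (permutation p = 2e-05), and r was 0.343 without 2 pigs. Without the 13 arrays that stand apart camera gave an adjusted p of 1.2e-18. Within the 10 blocks of title numbers r was positive in 9, from -0.467 to 0.831, and 0.334 with the block means removed.

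Immediate early genes, which respond within minutes to stress and growth signals, and genes of endoplasmic reticulum stress were lower with more fat by camera. Of 16 immediate early genes 0 had a positive slope; 1 fell over all genes tested, IER5, and 4 fell when adjusted over the list alone (camera adjusted p = 9.33e-12, but adjusted p = 0.122 with an estimated correlation and 0.063 with fry). ATF3, a stress-induced transcription factor, had a slope of -0.20 (SE 0.06, adjusted p = 0.196), KLF10 -0.13 (SE 0.044, adjusted p = 0.324) and MYC -0.14 (SE 0.052, adjusted p = 0.395). Of 18 genes of endoplasmic reticulum stress 0 had a positive slope; 1 fell over all genes, ASNS, and 8 fell when adjusted over the list alone (camera adjusted p = 1.68e-10, but adjusted p = 0.175 with an estimated correlation and 0.0941 with fry). ATF4, the transcription factor that turns on ASNS, had -0.10 (SE 0.03, adjusted p = 0.242), MANF, a stress-induced secreted protein, -0.14 (SE 0.048, adjusted p = 0.305) and DNAJB11, a chaperone, -0.11 (SE 0.037, adjusted p = 0.31). The mean of the immediate early list correlated with fat area at r = -0.252 (permutation p = 0.0019) and rho = -0.237 (permutation p = 0.00355), -0.253 without 2 pigs, and negatively in 7 of the 10 blocks (from -0.543 to 0.539). For endoplasmic reticulum stress r was -0.225 (permutation p = 0.00557) and rho -0.232 (permutation p = 0.00428), -0.208 without 2 pigs, and negative in 9 of the 10 blocks (from -0.593 to 0.378). With DBP, ARNTL and NFIL3 as covariates the median slope of immediate early genes went from -0.0872 to -0.0224 (95% bootstrap interval -0.0764 to 0.0134). That of endoplasmic reticulum stress went from -0.0547 to -0.0151 (interval -0.0413 to 0.0153). These covariates followed fat area themselves, so the smaller slopes do not show that the clock is the cause.

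**Figure D3:**
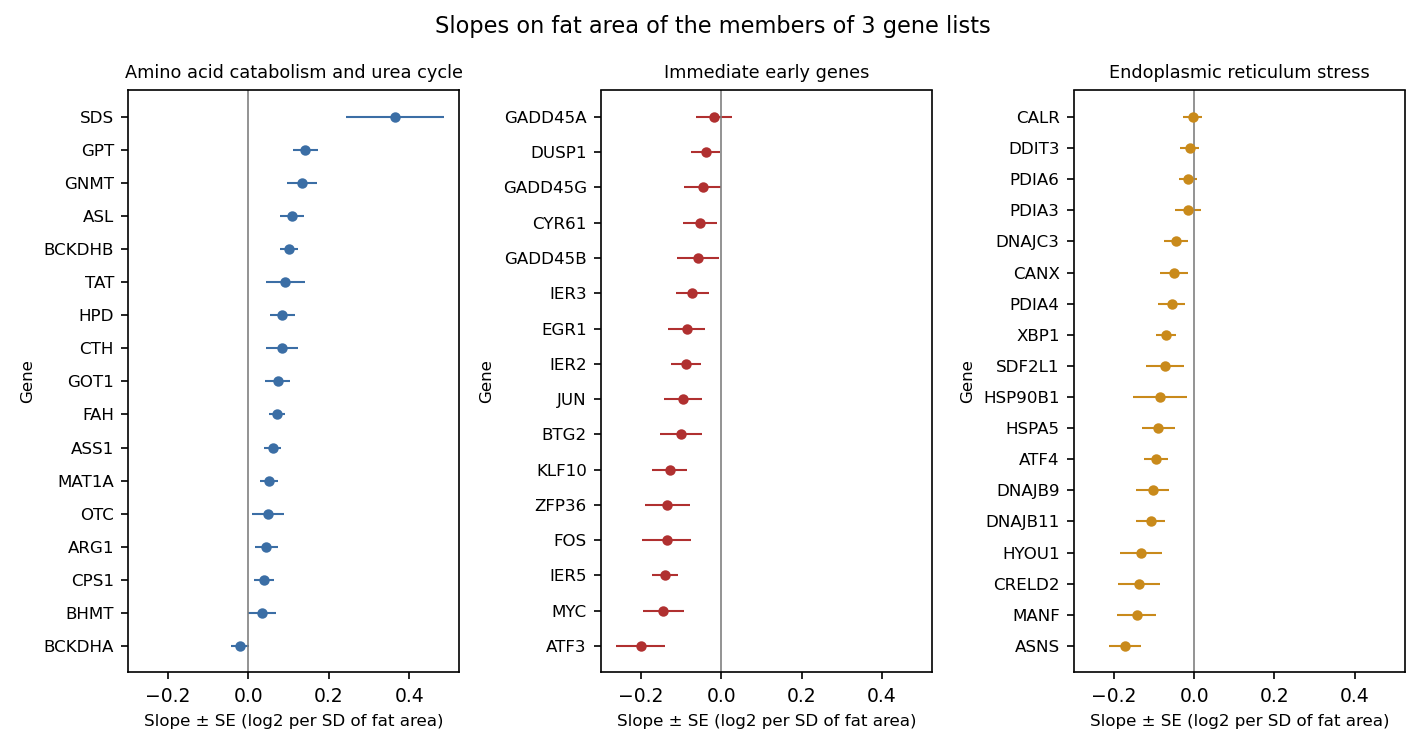
Slope on fat area (log2 per SD, with SE) of each measured gene, by its probe set of smallest p, in 3 gene lists. All but 1 of the 17 genes of amino acid catabolism and the urea cycle lie above 0, and the 16 immediate early genes and 18 genes of endoplasmic reticulum stress lie below it.

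Bile acid synthesis and transport was higher with fat area (camera adjusted p = 0.000544, but adjusted p = 0.175 with an estimated correlation). Over all genes 0 of its 8 passed, and 1 passed when adjusted over the list alone, CYP7A1, the rate-limiting enzyme of bile acid synthesis (slope 0.43, SE 0.121, adjusted p = 0.148 and 0.00415). With DBP, ARNTL and NFIL3 as covariates the list's median slope went from 0.041 to 0.0195 (95% bootstrap interval -0.00838 to 0.0472). Here too the covariates followed fat area themselves. Fatty acid and triglyceride synthesis was near the threshold (adjusted p = 0.0497, and adjusted p = 0.762 with an estimated correlation); 0 of its 17 genes passed over all genes and 1 over the list alone, AGPAT2, which makes phosphatidic acid (slope 0.08, SE 0.025). Without the 13 arrays that stand apart that list had an adjusted p of 0.291, and with 5 principal components its direction turned. Markers of skeletal muscle were also near it (adjusted p = 0.0497, and adjusted p = 0.433 with an estimated correlation), and of the 13 only CA3, a carbonic anhydrase also made in liver, passed over the list alone (slope 0.38, SE 0.096, adjusted p = 0.0689 over all genes). The list of Y-linked genes, of which 2 were measured, had an adjusted p of 0.0484 (adjusted p = 0.175 with an estimated correlation). Of the 2 only EIF1AY had a positive slope, and the correlation between them was estimated at -0.0259, so the result of this list rests on EIF1AY. The mean of the 2 mostly followed EIF1AY, with r = 0.983.

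Lists lower with more fat by the preset test also included cytosolic ribosomal proteins (adjusted p = 0.0171, and adjusted p = 0.825 with an estimated correlation), the interferon response (0.0171, and adjusted p = 0.959 with an estimated correlation), acute phase proteins (0.0225, and adjusted p = 0.528 with an estimated correlation) and antigen presentation (0.0261, and adjusted p = 0.747 with an estimated correlation). Of their genes 0 of 59, 0 of 20, 0 of 16 and 1 of 16 passed over all genes, the last being the B2M probe set named above. Without the 13 arrays that stand apart the adjusted p was 0.546 for the interferon response and 0.0604 for antigen presentation; with the Y-linked mean as a covariate it was 0.685 for ribosomal proteins. The circadian list did not pass as a whole (adjusted p = 0.902), with DBP up over all genes and NFIL3 (slope -0.14, SE 0.046) and ARNTL (slope -0.12, SE 0.046) lower when adjusted over the list alone. Camera tests a shift of a list in a single direction, so members with opposite slopes cancel in it. Antioxidant defence did not pass (adjusted p = 0.253), with PRDX6 its member past the test.

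The remaining lists did not pass with fat area. Adjusted p values of the metabolic lists were 0.155 for lipoproteins and lipid transport, 0.155 for xenobiotic metabolism, 0.235 for oxidative phosphorylation, 0.253 for glucose and glycogen metabolism, 0.902 for fatty acid oxidation and 0.918 for cholesterol synthesis. Within fatty acid oxidation PLIN2, a coat protein of lipid droplets, had a slope of -0.32 (SE 0.081, adjusted p = 0.0637) and CPT1A, which brings fatty acids into mitochondria, -0.20 (SE 0.06, adjusted p = 0.214), both lower when adjusted over the list alone. The values were 0.26 for the cell cycle, 0.461 for the heat shock response, 0.745 for secreted plasma proteins, 0.864 for the glucocorticoid response and 0.866 for the growth hormone and IGF axis. Among cell type markers they were 0.0611 for red blood cells, 0.414 for neutrophils, 0.474 for T and NK cells, 0.71 for endothelial cells, 0.745 for stellate cells and fibroblasts and 0.784 for adipocytes. They were 0.864 for exocrine pancreas, 0.918 for bile duct cells, 0.931 for B and plasma cells and 0.945 for macrophages. The median slope, mean slope and test differed in sign for 5 of these lists and for 0 of the 11 that passed.

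With drip loss, 0 of 23999 probe sets passed limma's test, the smallest adjusted p being 0.215. At an unadjusted p under 0.05 there were 2638, 1345 higher and 1293 lower, against 1200 expected from uniform p values. The number was 1284 with the spline of the title number as a covariate and 1506 with the array median. None of the genes named below passed. Of smallest p among negative slopes were MYO1C, an unconventional myosin (slope -0.09, SE 0.019, adjusted p = 0.215), CSTF1, an mRNA cleavage factor (-0.09, SE 0.021, adjusted p = 0.284), a GAPDH probe set (-0.10, SE 0.023, adjusted p = 0.284), MYL9, a smooth muscle myosin light chain (-0.10, SE 0.023, adjusted p = 0.307), and TNFRSF21, a death receptor (-0.09, SE 0.024, adjusted p = 0.307). The brightest GAPDH probe set had a slope of -0.0032 (p = 0.82), and a brighter CSTF1 probe set -0.023 (p = 0.296). Among positive slopes they were RAB23, a small GTPase (0.07, SE 0.017), KIF3A, a kinesin (0.06, SE 0.017), CLDN12, a claudin (0.22, SE 0.06), TEX30 (0.08, SE 0.022) and TMBIM6, an inhibitor of cell death (0.07, SE 0.018), with adjusted p values from 0.307 to 0.309. The 3 other KIF3A probe sets had slopes of -0.0089, -0.00026 and 0.02 (p from 0.139 to 0.988), and the brighter TMBIM6 probe set 0.012 (p = 0.468).

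Taken singly, MYO1C correlated with drip loss at r = -0.357 (permutation p = 2e-05) and rho = -0.334 (permutation p = 7e-05), CSTF1 at r = -0.328 (permutation p = 7e-05) and rho = -0.334 (permutation p = 5e-05), and the GAPDH probe set at r = -0.326 (permutation p = 6e-05) and rho = -0.298 (permutation p = 0.00028). RAB23 had r = 0.305 (permutation p = 0.00013) and rho = 0.298 (permutation p = 0.00016), KIF3A r = 0.287 (permutation p = 0.00045) and rho = 0.276 (permutation p = 0.0008), and CLDN12 r = 0.284 (permutation p = 0.00046) and rho = 0.295 (permutation p = 0.00023). These were picked as the smallest of 23999 p values, and the permutation p does not allow for that. Without 2 pigs r was -0.364, -0.331, -0.334, 0.309, 0.271 and 0.259 in the same order. Given the spline of the title number the partial r was -0.314, -0.26, -0.289, 0.256, 0.253 and 0.227. Adjusted over the 12 relations, p of r was at most 0.00046 and p of rho at most 0.0008.

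Of the lists, 5 were lower with drip loss by the preset test, and 0 passed with an estimated correlation or with fry. Antigen presentation had an adjusted p of 3.38e-05 (adjusted p = 0.343 with an estimated correlation), and its 16 genes had 0 positive slopes. In that list SLA-DMA (slope -0.10, SE 0.037), SLA-DMB (-0.08, SE 0.033) and CD74 (-0.09, SE 0.038), which serve MHC class II, and B2M (-0.06, SE 0.023) had adjusted p values from 0.34 to 0.386. The other 8 B2M probe sets had slopes from -0.042 to 0.021 and correlated with this one at -0.271 to 0.429, and a brighter SLA-DMA probe set had a slope of -0.022 and r = 0.00578 with the one named. Markers of macrophages and Kupffer cells, the resident macrophages of the liver, had an adjusted p of 0.00507 (adjusted p = 0.517 with an estimated correlation), with TYROBP (-0.08, SE 0.027), SPI1 (-0.07, SE 0.034), VSIG4 (-0.07, SE 0.034) and C1QC (-0.06, SE 0.029) at adjusted p values from 0.314 to 0.451. Oxidative phosphorylation had 0.0204 (adjusted p = 0.762 with an estimated correlation), with NDUFB8 (-0.05, SE 0.019), NDUFS3 (-0.05, SE 0.023) and ATP5D (-0.04, SE 0.018) negative and NDUFS1 positive (0.06, SE 0.024), none past the test. Endothelial markers had 0.0261 (adjusted p = 0.613 with an estimated correlation) and markers of stellate cells and fibroblasts 0.0364 (adjusted p = 0.528 with an estimated correlation). Over all genes 0 members of these lists passed; over the list alone 1 macrophage, 2 endothelial and 2 stellate cell markers were lower. Without the 13 arrays that stand apart the adjusted p was 0.159 for macrophages, 0.288 for oxidative phosphorylation and 0.2 for endothelial cells. With the 3 prime to 5 prime differences as covariates only antigen presentation of these 5 passed (adjusted p = 0.000933), the others lying between 0.0552 and 0.493, and with 5 principal components none of the 5 did (adjusted p from 0.12 to 0.576, and 0.275 for antigen presentation). Bile acid synthesis and cytosolic ribosomal proteins were then higher with the 3 prime to 5 prime differences (adjusted p = 0.0282 and 0.0265).

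The other 29 lists did not pass with drip loss. Adjusted p values were 0.0544 for skeletal muscle, 0.0728 for glucose and glycogen metabolism, 0.0801 for the heat shock response, 0.141 for T and NK cells, 0.155 for bile acids, 0.253 for the growth hormone and IGF axis and 0.297 for lipoproteins. The rest ran from 0.634 for cytosolic ribosomal proteins to 0.948 for amino acid catabolism. Among the 29, the median slope, mean slope and test differed in sign for 10.

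The slopes on the traits differed for 2 probe sets, both with a higher slope on fat area and both also called for fat area: CST3 (difference 0.12, SE 0.025, adjusted p = 0.0331; 0.08 on fat area and -0.05 on drip loss) and the probe set without a symbol that stayed called with the Y-linked mean (difference 0.24, SE 0.05, adjusted p = 0.0405). QDPR, which regenerates the cofactor of aromatic amino acid hydroxylases, had a difference of 0.18 (SE 0.038, adjusted p = 0.0628), DBP 0.29 (SE 0.067), MCRIP2 0.16 (SE 0.038) and PRKD2 0.15 (SE 0.035), the last 3 at an adjusted p of 0.0777. In the other direction RNASEH2B, TEX30, MCUR1, PTPN2 and BAG5 had adjusted p values from 0.202 to 0.303. Without the 2 most extreme pigs 14 probe sets differed. Across the 23999 probe sets, which are not independent replicates, the slopes on the traits correlated at r = 0.0262, against -0.598 to 0.471 when the pairs of traits were permuted over the pigs (p = 0.92 over 99 permutations). The covariance was 2.87e-05, against a median of -4.01e-05 in the permutations.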

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

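The array median, and the Y-linked mean together with 5 principal components, were chosen as covariates after seeing the data. Of 30 probe sets called for fat area in the fit without covariates, other settings called 46 (SD above 0.25), 18 (normal scores of expression and trait), 48 (3 prime to 5 prime differences), 1.0e+02 (5 principal components; 68 higher and 34 lower), 1 (Y-linked mean), 46 (without arrays that stand apart), 59 (array median), 1 (Y-linked mean and 5 principal components), 7 (adjusted p under 0.01) and 66 (adjusted p under 0.10); other counts lay between 26 and 45. Stricter or looser thresholds act by construction, and a filter leaves fewer probe sets to adjust over; otherwise the cause was not tested. For drip loss 0 were called in each setting but the Y-linked mean and 5 principal components, with 1 (RNASEH2B, slope 0.09, SE 0.018, adjusted p = 0.0435). Slopes differed between the traits for 14 probe sets instead of 2 without the 2 most extreme pigs, all higher for fat area. The list of fatty acid and triglyceride synthesis turned its direction with fat area under 5 principal components, at an adjusted p of 0.502. The correlation between the traits and that between the slopes stayed near 0. Named genes kept their direction for both traits: for fat area 356 values stayed on their side of the threshold, 48 lost it and 11 gained it, and for drip loss 408 stayed. The 13 named genes called for fat area all lost their call with the Y-linked mean. Of the values of the 11 and 5 lists past the preset test, 71 and 29 kept the call for fat area and drip loss, and 48 and 26 lost it. Lists not past it gained a call 3 times for fat area (red blood cells under 2 settings, heat shock) and 7 times for drip loss (heat shock and ribosomal proteins under 2 settings each, bile acids, the growth hormone axis, and the interferon response, which turned to higher with 5 principal components at an adjusted p of 0.000135). A planned fit with surrogate variables suits array values and was tried, but it was left out because its package was allowed for counts only. In that run more probe sets were called for fat area. No value of it was kept, so this cannot be checked and nothing here rests on it. The choice of log transform was void because the values are deposited as logs. No paired analysis was possible because the pigs form a single group. Signal near the floor of 4.09 limits dim probe sets, of which 177 lay at it on most arrays.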

Other observations

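The tests of the level of Y-linked transcripts, on the probe sets that track it and on the gene list, were chosen, or their bounds set, only after the results were seen. The same holds for the tests of the quality measures on the gene list, of the title number and array brightness, and of the permuted traits. The split-pig tests and the clock test of the amino acid catabolism list were set beforehand. The clock genes used, DBP, ARNTL and NFIL3, are however the circadian genes that passed with fat area when adjusted over the list alone. As covariates they can therefore take up part of a slope on fat area.

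Several livers stood far from the others on 1 or more gene lists. In the interferon response, 6 pigs lay over 5 MAD from the median of the list, led by pig 70 (16.7 MAD) and pig 54 (12.4 MAD). RSAD2, an antiviral enzyme, reached 15.77 and 15.3 on the log2 scale in these pigs against a median of 8.7, ISG15 13.23 and 13.11 against 8.33, and MX1 13.07 and 12.54 against 8.03. Pig 70, with a fat area of 11.5 cm2 and a drip loss of 6.69%, was also the lowest for xenobiotic metabolism, glucose metabolism, oxidative phosphorylation and amino acid catabolism, at -4.84, -4.38, -4.21 and -3.06 MAD, and its array was among those that stand apart. In another pig the heat shock list lay 8.55 MAD above the median: HSPA6, a strictly inducible chaperone, was at 12.48 where the next pig had 6 and the median was 5.53, HSPH1 was at 11.7 against 6.57 and DNAJB1 at 12.97 against 8.89. That pig also led the immediate early list, at 5.36 MAD, and its array did not stand apart.

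Clock genes were related to each other across the pigs; the time of slaughter is not in the labels. DBP and ARNTL, which peak at opposite times of day in rodent liver, had r = -0.668 and rho = -0.727, and DBP and NFIL3, which compete for the same sites, r = -0.571 and rho = -0.56 (permutation p = 1e-05 for each, the smallest possible; adjusted p = 2e-05 over 6 relations; r = -0.672 and -0.555 without the 2 pigs of most extreme DBP). ARNTL and NFIL3 had r = 0.471 and rho = 0.475 (permutation p = 1e-05 for each; 0.481 without 2 pigs). DBP and CYP7A1 had r = 0.323 (permutation p = 9e-05) and rho = 0.233 (permutation p = 0.00404), and r was 0.251 without 2 pigs. DBP and PER1 had r = 0.275 (permutation p = 0.00072) and rho = 0.306 (permutation p = 0.00012), and ARNTL and ASNS r = 0.183 (permutation p = 0.0238) and rho = 0.145 (permutation p = 0.0781), and r was 0.322 and 0.192 without 2 pigs.

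Some probe sets had 2 separate levels. A gap of over 2 on the log2 scale with at least 5 pigs on each side occurred in 6 probe sets, 3 of which track the Y-linked mean. These 3 were called for fat area. Their r with that mean was 0.942, 0.963 and -0.915, and they were high in 77, 77 and 73 pigs in the same order. The clusters of EIF1AY held the same numbers of pigs, 77 and 73. A probe set annotated as GSTA1, a glutathione transferase, had a median of 13.46 in 10 pigs and 4.65 in the other 140, with a gap of 6.69, while another GSTA1 probe set ran from 12.6 to 13.72 in all pigs. A probe set without a symbol lay at 5.2 or less in 5 pigs and at 10.17 or more in all others, and 0 of those 5 were among the 10. Fisher's exact test did not tell this overlap from chance. Neither followed fat area (p = 0.913 and 0.747) or drip loss (p = 0.424 and 0.721).

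Of 100 assignments of the traits to the pigs, the real one included, 2 called as many as the 30 probe sets called for fat area. Chance was therefore an unlikely source of the count, but it was not excluded. The other assignment called 73, more than the real one, as can happen where many probe sets vary together over the pigs. The 10 probe sets that track the Y-linked mean kept 0.116 of their median slope with that mean as a covariate. The 95% bootstrap interval of this ratio was -0.00501 to 0.248. They were chosen for their correlation with that mean, and EIF1AY is part of it, so the choice fixed the outcome and the ratio decides nothing. Within the lower and upper cluster of EIF1AY values r with fat area was -0.0619 and -0.0746. The rise of EIF1AY with fat area therefore lay between its clusters, not within them. The labels do not give sex, and no pig was assigned one. A difference between the sexes was therefore not tested and stays open for these calls. For the other 20, whose low correlation with the mean leaves little room for change, the ratio was 0.904 (interval 0.768 to 1.05) and 20 of 20 kept an unadjusted p under 0.05; their median slope went from 0.142 to 0.128 and the median SE from 0.0314 to 0.0332, yet only 1 of them kept an adjusted p under 0.05. For 30 probe sets chosen in 75 pigs among those with an absolute r of at most 0.5 with the Y-linked mean, the mean slope in the other 75 was 0.109 SD per SD (median of 100 splits), 0.0941 with the Y-linked mean and 0.124 with the quality measures as covariates, with 1, 4 and 1 splits at or below 0. Fewer than 5 had been set as the bound against each explanation, so the test of the Y-linked mean was borderline. The quality measures were hardly related to fat area, so as covariates they could hardly change the result. The splits share pigs, and sex, age, feeding, family and slaughter day stay open.

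The rise of amino acid catabolism with fat area was set against 3 explanations. The list's median slope of 0.0778 (95% bootstrap interval 0.0465 to 0.109) was 0.0622 (0.0217 to 0.09) with the Y-linked mean, 0.0772 (0.0452 to 0.108) with the 3 prime to 5 prime differences and the array median, and 0.0748 (0.0457 to 0.11) with the 3 clock genes as covariates. Each interval lies above 0, which argues against the 3 clock genes, as measured here, as the whole cause. The Y-linked mean as a covariate did not fully remove the slopes of the 10 called probe sets that track it. With it, 10 kept their sign and 3 kept an unadjusted p under 0.05 in limma. The interval with that mean therefore does not decide whether what lies behind the Y-linked transcripts is the cause. The quality measures were hardly related to fat area. Pearson's r was -0.0142 for the GAPDH difference, 0.0132 for the actin difference and 0.0045 for the array median. As covariates they could therefore hardly change the slope. Sex, feeding state before slaughter, protein supply and family are not in the labels and stay open.

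The excess of small p values with drip loss may not be a relation to drip loss at all. Of 100 assignments of the traits, 8 gave as many probe sets with an unadjusted p under 0.05 as the real 2638, the highest other being 6160, so chance could not be excluded; for fat area it was 16 of 100 at the real 1699, the highest other being 4820, with the same outcome. With the spline of the title number as a covariate the number was 1284 and with the array median 1506, against 1200 from uniform p values, so the order behind the titles or array brightness may also account for it. Since drip loss itself went with the title number, removing the title number can remove real relations too, and no biological explanation was tested. For the 2 probe sets whose slopes differed between the traits, 4 of 100 assignments called as many, the others being 6, 48 and 59. That share lies just under 0.05, so chance was not excluded. The permutation also removes the relations to both traits at once, and both probe sets were called for fat area. It therefore does not test the difference of the slopes alone.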
